A study of Mus musculus with 4 samples.

How the data were processed

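The series held 4 one-colour arrays of total RNA from mouse primary kidney tubular cells, 2 from wild type and 2 from SerpinB2-/- mice. Per the labels, the mice were 8 weeks old with a B6.J background, every culture was treated with the phorbol ester PMA at 100 ng/ml, and 150 ng of RNA entered the labelling with Cy3. Samples were grouped by the genotype label. Their numbers were taken from the titles, and no label says whether a number marks an animal, a litter or a day. The series had no untreated cells, so the response to PMA itself was not measured.

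The deposited files held one scanner output per array. Per the file headers, Agilent Feature Extraction 10.7.3.1 had made the intensity values by subtracting a background, removing spatial and multiplicative trends and replacing the values of dim spots with surrogates. The deposited intensity of each array was used as it stood in these files. All 4 arrays lay on 1 slide and were scanned together, per the file headers, so slide and scan could not differ between the groups. The wild type arrays held the first positions on the slide and the SerpinB2-/- arrays the last, and position cannot be separated from genotype. The series also held a deposited table of the authors' processed values. Each of its columns had a 75th percentile of 1500 and a floor of 4 on a linear scale, and followed the scanner intensity of its array by a single factor of 0.698 to 0.787 (94.6% to 95.7% of probes within 5%). Its medians were 76 and 77 for wild type and 68 and 71 for SerpinB2-/-. No centring of genes was found in it, and the labels do not describe how it was made.

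The array carried 39429 probes for transcripts, each printed 4 times, besides 17263 control spots. Control spots and spots marked as outliers by the scanner software were left out, and the remaining spots of a probe were averaged. The 75th percentile of the log2 signal was subtracted on each array. A probe was used if more than 50% of its spots were well above background, as the scanner software marks it, on both arrays of at least 1 genotype. The brightest such probe stood for its gene. Probe names were matched to a reference gene table of assembly GRCm38.p6 (28328 probes by accession, of which 1359 took a new symbol, and 243 by an older symbol), and no coordinate was taken from it. Positions come from the files, which use build mm9 (NCBI37). Between 23409 and 24476 probes per array were well above background, and no spot was saturated. The number of arrays limits the precision.

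The 18392 genes were compared with limma 3.58.1 in R 4.3.3 (linear model and moderated test, eBayes without trend), as SerpinB2-/- minus wild type, with Benjamini-Hochberg adjustment and a threshold of 0.05. Where a probe was not well above background on either array of a group, only a bound is given as "at least N-fold". The bound sets the mean of the bright group against, per array of the dim group, the higher of the probe's own signal and the lowest signal among probes well above background. Where 1 array of a group was dim and lay below that lowest signal, the log2 change with this limit is given. The 27 gene lists held 802 genes, of which 672 were measured. They were tested with limma's camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, which tests a list against no change where camera tests it against other genes, each adjusted over the 27 lists. Genes were named by a rule: Serpinb2; the 12 highest and 12 lowest log2 changes past the threshold whose groups did not overlap, without predicted or clone names; in each list up to 4 members past the threshold with the largest change; and 14 genes of inflammation, plasminogen activation, tubular injury and strain. These lists, this rule, the tests named in this paragraph and most alternatives were fixed before the data were examined. Some tests of explanations were chosen later, as stated where they are given.

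The procedure was tested on simulated data for this comparison with 18392 genes and the spread of the real fit. Of the genes changed 4-fold, 97% were recovered, of those changed 2-fold 79.1%, and of those changed 1.41-fold 26.9%. Of 141 simulated calls 6 were false, and simulated data without any change gave 0 calls. The simulation changed 200 genes and drew normal errors independently for each gene. Spread shared by the genes of an array was not simulated, so these counts do not give the error rate of the real calls.

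The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling by the median or by the 75th percentile of detected probes, the authors' table, other filters on dim probes, the mean of a gene's probes or every probe by itself, a trended, robust or array-weighted fit, the replicate number as a block, each array left out, other thresholds and an unmoderated two-group test. Spots marked as outliers kept, a 20 Mb window on chromosome 1 left out, and lists without Serpinb2 and Serpinb10 were added after the data were seen. Fisher's exact test compared shares of genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.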

Results

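Gene expression was measured in primary kidney tubular cells, cultured from mouse kidney and exposed to PMA, a phorbol ester that activates protein kinase C. The series title gives the question as the part that plasminogen activator inhibitor-2, the product of Serpinb2, plays in the immune response to kidney injury and in renal ageing. There were 2 wild type and 2 SerpinB2-/- samples, each on its own array. The 75th percentile of the signal lay between 1904 and 2143 units and was 314 to 385 times the median of the negative controls. The 2 wild type arrays differed by a median of 0.08 on the log2 scale, as did the 2 SerpinB2-/- arrays, against 0.14 to 0.16 between arrays of different genotype. The median squared difference between 2 arrays was divided by the median variance that the spread between spots gives to such a difference of probe means. This ratio of medians was 3.32 and 2.49 within a genotype and 8.45 to 11.1 across genotypes. The labels do not say that the samples came from separate cultures or animals. All p-values therefore measure only the spread between these samples, and with 2 samples against 2 the smallest exact two-sided p of a single gene would be 0.333.

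Serpinb2 was the gene with the lowest value in SerpinB2-/- cells relative to wild type. Its probe, on chromosome 1 at 109422046 to 109422105 (mm9), gave 3047 and 3383 signal units in wild type and 5.88 and 7.21 in SerpinB2-/- cells, where it was not well above background. Set against the lowest signal that counts as well above background on each array, this is at least 140-fold lower (adjusted p = 0.000711 by limma with Benjamini-Hochberg adjustment). Its neighbour Serpinb10, a clade B serpin of myeloid cells, showed the opposite. It was not well above background in either wild type sample and was at least 67.0-fold higher in both SerpinB2-/- samples (adjusted p = 0.00116). With normexp background correction, which raises dim signals by an offset, the log2 change was -5.69 for Serpinb2 and 4.72 for Serpinb10. The labels do not state which part of Serpinb2 was deleted, nor whether the probe lies in it.

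**Figure D1:**
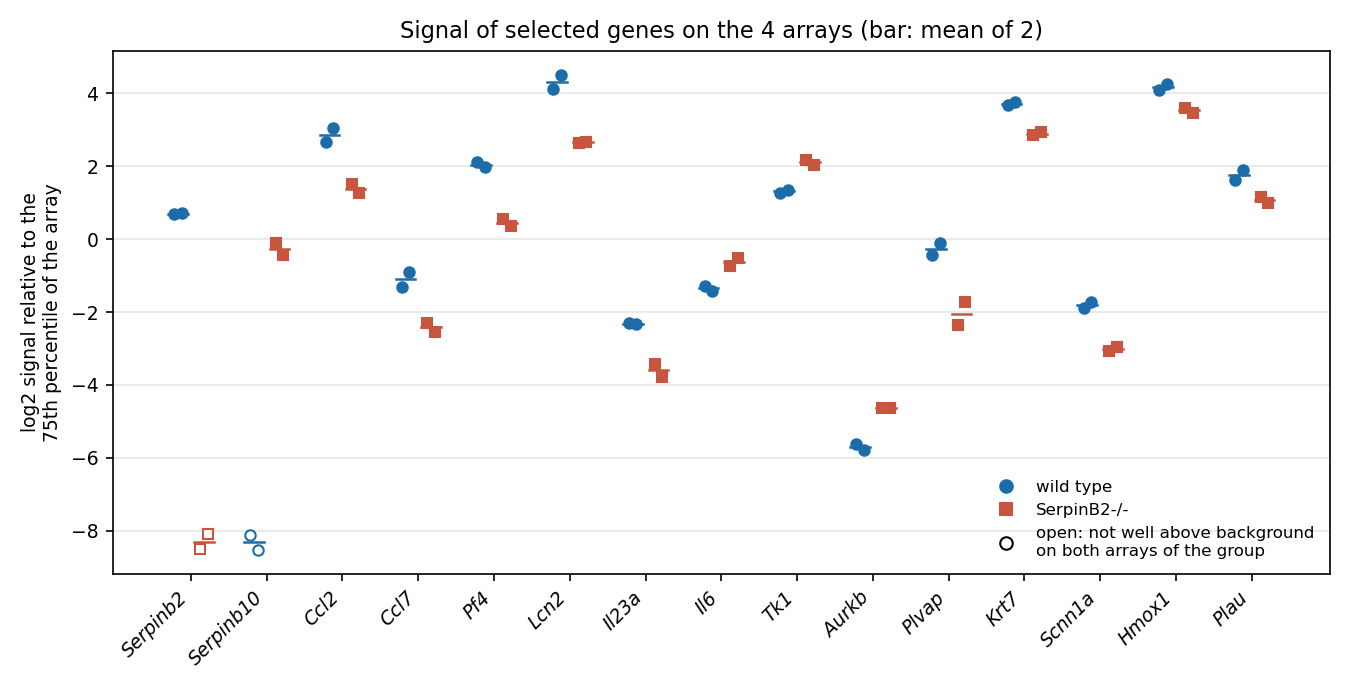
Signal of 15 genes on the 4 arrays, as log2 relative to the 75th percentile of the array (vertical axis), with 1 point per array and a bar at the mean of 2. Open symbols mark a group in which the gene was not well above background on both arrays. Ccl2 had a mean of 2.85 in wild type and 1.39 in SerpinB2-/- cells, and Tk1 a mean of 1.31 and 2.10.

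Beyond the locus, gene lists differed by camera at a preset correlation between genes. SerpinB2-/- cells had lower transcripts of chemokines, antigen presentation, leukocyte, endothelial, and urothelial and squamous epithelial genes, and higher transcripts of the cell cycle. None of the 15 list calls held with an estimated correlation (lowest adjusted p = 0.278). Camera with an estimate also draws on the few residual degrees of freedom left by 4 arrays, so few lists could pass whatever their correlation. For interferon-stimulated genes and NRF2 targets the estimate (-0.020 and -0.012) lay below the preset 0.01. Their unadjusted camera p still rose, from 1.1e-05 and 2.42e-05 to 0.0384 and 0.0411. Of 18392 genes tested, 2877 passed the threshold (15.6%), 1099 higher and 1778 lower. A change of at least 2-fold was seen for 31 higher and 224 lower genes. The groups did not overlap for 64.4% of genes, where chance gives 33.3%. The count was 4 without wild type replicate 2 and 436 without wild type replicate 1, and 1779 and 1603 without SerpinB2-/- replicate 1 or 2. It was also 3 with dim probes kept, 4773 with median scaling, which moved the median of all genes to 0.13 and turned the balance to 3532 higher and 1241 lower, and 0 with an unmoderated test (4456 genes at an unadjusted p under 0.05). The size of the change depended on the background method for dim genes: with normexp 39 of 115 named genes past the threshold had a log2 change smaller by over 1.5 times, and 33 of the 39 still passed.

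The 12 highest genes were Serpinb10 and, after it, Folh1, which encodes the folate hydrolase also known as prostate-specific membrane antigen (2.58 ± 0.17 log2, SE, n = 2 per group), the X-linked Xlr4b and Xlr4a (2.03 and 1.89), the activin and inhibin subunit Inhbb (1.93 ± 0.08), the heparan sulphate proteoglycan Gpc3 (1.48), the fibrinogen chain Fgb (1.38), the hyaluronan receptor Lyve1 (1.37), the matrix protein Thbs2 (1.33), and Igsf21, Pam and Cracdl. Igsf21, an immunoglobulin superfamily gene, rose by at least 1.88. It and Gpc3 were well above background on 1 of the 2 wild type arrays, and with the other array at its detection limit Gpc3 was at 1.45. Pam, an enzyme of peptide amidation, rose by 1.73 at its brightest probe, while a further dim probe gave -0.28. Cracdl gave 1.59 and 0.73 at its 2 probes. The 12 lowest genes were Serpinb2, Apob, the apolipoprotein of lipid-carrying particles (at least 4.40-fold lower), the neuronal adhesion gene Cntnap5a (at least 3.47-fold), the lymphocyte GTPase Gimap5 (at least 2.998-fold), the polysialyltransferase St8sia4 (at least 2.67-fold), the homeobox gene Meox1 (at least 2.61-fold), Plekhd1 (at least 1.54-fold), Ifitm6 (at least 1.45-fold), and Stk25, Padi4, Nkx2-3 and Snhg11. The kinase Stk25, the arginine deiminase Padi4, the homeobox gene Nkx2-3 and the non-coding Snhg11 fell by 1.85, 1.90, 1.89 and 1.85, Padi4 being well above background on 1 of the 2 SerpinB2-/- arrays. Each of these genes had an adjusted p of 0.0265 or less. With normexp the log2 change was 1.27 for Xlr4b, 1.25 for Xlr4a, 0.97 for Igsf21, 0.64 for Gpc3, 0.92 for Fgb and 0.83 for Lyve1. It was -1.03 for Apob, -1.05 for Cntnap5a, -0.67 for Gimap5, -0.63 for St8sia4, -0.61 for Meox1, -0.44 for Ifitm6, -0.88 for Padi4, -1.21 for Nkx2-3, -0.97 for Snhg11 and -0.42 for Plekhd1, which then no longer passed (adjusted p = 0.0664). The bounds thus hold for the scanner's processed signal only. The places of genes with a bound among the 12 lowest rest on fitted values. Ifitm6 and Plekhd1 were bounded at 1.45-fold and 1.54-fold. Plvap, well above background in both groups and not among the 12, fell 3.42-fold at its brightest probe.

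Chemokines were lower in SerpinB2-/- cells. The monocyte attractants Ccl2, Ccl7 and Ccl12 fell by 1.46 ± 0.16, 1.31 ± 0.17 and 1.54 ± 0.23 (log2, SE, adjusted p = 0.0109, 0.0145 and 0.0200), and platelet factor Pf4 fell by 1.58 ± 0.09 (adjusted p = 0.00712). Of 22 measured chemokines 9 fell and 0 rose over all genes, and 12 fell and 1 rose when adjusted over the list alone. The neutrophil attractant Cxcl1 differed by -0.14 ± 0.24 (adjusted p = 0.714). The list lay below other genes by camera (adjusted p = 0.000351), with adjusted p = 0.476 with an estimated correlation. Fry, which tests a list against no change and not against other genes, gave 0.110. Leukocyte and macrophage markers were lower in the same samples, with a list median of -0.50.

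Among inflammatory cytokines and NF-kB targets, 7 of 31 fell and 1 rose, and 8 fell and 1 rose adjusted over the list alone. Lcn2, the iron-binding lipocalin used as a marker of tubular damage, fell by 1.67 ± 0.14 (adjusted p = 0.00775), Icam1 by 1.06 ± 0.06, Il23a by 1.28 ± 0.13 and Tnf by 1.27 ± 0.22. Tnf was well above background on 1 of the 2 SerpinB2-/- arrays. With normexp Icam1 and Tnf fell by 0.58 and 0.48. Il6 went the other way, with a rise of 0.73 ± 0.10 (adjusted p = 0.0177). Csf1 differed by -0.11 ± 0.09 (adjusted p = 0.419) at its brightest probe, its 3 probes ranging from -0.42 to -0.11. With the mean of its probes Csf1 passed (-0.30, adjusted p = 0.0389 by limma). Il1b was not well above background and was not tested. The list was lower by camera (adjusted p = 0.0141), with adjusted p = 0.622 with an estimated correlation. Against no change it did not pass either (0.273 by fry). The camera call ended without wild type replicate 2 (adjusted p = 0.106) and without SerpinB2-/- replicate 2 (0.141), and the list's median of -0.10 became 0.02 with median scaling. The leukocyte list was lower here as well.

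Genes of antigen presentation and of the interferon response were lower. Of 23 antigen presentation genes 12 fell and 0 rose, and 16 fell adjusted over the list alone. The peptide transporter Tap1 fell by 1.05 ± 0.08, the class II invariant chain Cd74 by 0.69 ± 0.06, the immunoproteasome subunit Psmb9 by 0.69 ± 0.08 and the class II chain H2-Ab1 by 0.67 ± 0.08. With normexp the falls of Tap1, Cd74 and Psmb9 were 0.50, 0.35 and 0.41. Of 28 interferon-stimulated genes 8 fell and 0 rose, and 13 fell adjusted over the list alone, with Ifit3 at -0.76 ± 0.11 and Oas1a at -0.71 ± 0.13. By camera the adjusted p was 1.74e-07 for antigen presentation and 4.94e-05 for interferon-stimulated genes. These were adjusted p = 0.433 and adjusted p = 0.278 with an estimated correlation. Against no change, by fry, both lists passed (adjusted p = 0.026 for each). The leukocyte markers were again lower in the same samples.

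Markers of other cell types differed between the genotypes. Of 27 leukocyte and macrophage markers 12 fell and 0 rose, and 16 fell adjusted over the list alone. They included the Fc receptor Fcgr1 (-1.08 ± 0.06), the granulocyte antigen Ly6g (-1.28 ± 0.09), the actin regulator Coro1a (-1.02 ± 0.10) and Laptm5 (-0.88 ± 0.19). Of 19 endothelial markers 13 fell and 2 rose, and 15 fell and 2 rose adjusted over the list alone. Plvap, of the diaphragm of fenestrated endothelium, fell by 1.78 ± 0.23 (1.07 at a further probe), Robo4 by 1.77 ± 0.22 and Sox17 by 1.68 ± 0.25. Tie1, well above background on 1 of the 2 SerpinB2-/- arrays, fell by at least 1.52. The rises were in Lyve1 and Flt1 (0.77 ± 0.06). With normexp Fcgr1, Tie1 and Sox17 fell by 0.56, 0.63 and 0.82. Fibroblast and pericyte genes went the other way. Of 27, 7 rose and 1 fell, and 12 rose and 3 fell adjusted over the list alone, with the matrix genes Postn at 1.09 ± 0.16, Col6a3 at 0.98 ± 0.07 and Mfap5 at 0.95 ± 0.18. Meox1 was the member that fell. The camera tests gave an adjusted p of 1.74e-07 for leukocyte, 4.12e-05 for endothelial and 0.00216 for fibroblast genes. With an estimated correlation they were adjusted p = 0.476, adjusted p = 0.491 and adjusted p = 0.622. Against no change, by fry, none of these lists passed (adjusted p = 0.0732, 0.0910 and 0.281).

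Cell cycle transcripts were higher in SerpinB2-/- cells. Of 39 proliferation genes 35 rose and 0 fell, and 39 rose adjusted over the list alone, with a list median of 0.51. The mitotic kinase Aurkb rose by 1.06 ± 0.08, thymidine kinase Tk1 by 0.79 ± 0.07, the spindle checkpoint kinase Ttk by 0.76 ± 0.09 and Hmgb2 by 0.68 ± 0.08 (adjusted p = 0.00712, 0.00893, 0.0127 and 0.0135). With normexp the rises of Aurkb and Ttk were 0.46 and 0.49. The list had an adjusted p of 4.52e-20 by camera and adjusted p = 0.278 with an estimated correlation. Against no change it passed by fry (adjusted p = 0.0150). Of 29 senescence and p53 genes 5 fell and 0 rose, and 6 fell adjusted over the list alone. The inhibitors of cyclin-dependent kinases Cdkn2a and Cdkn2b fell by 0.49 ± 0.10 and 0.40 ± 0.09, Igfbp3 by 0.91 ± 0.13 and Perp by 0.75 ± 0.08. Cdkn1a differed by -0.15 ± 0.07 (adjusted p = 0.196) at its brightest probe, its probes ranging from -1.01 to -0.15. With the mean of its probes Cdkn1a passed (-0.54, adjusted p = 0.0254 by limma). Camera gave an adjusted p of 0.0280 for the senescence and p53 list, with adjusted p = 0.622 with an estimated correlation. Against no change, by fry, it did not pass (adjusted p = 0.218). The camera call ended without genes of more than 1 list (0.0809), without wild type replicate 1 (0.151) and without SerpinB2-/- replicate 1 (0.123), and the list's median of -0.09 became 0.03 with median scaling. Fibroblast and pericyte genes were higher in the same samples as the cell cycle genes, with a list median of 0.31.

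Genes of the urothelial and squamous epithelial list were lower in SerpinB2-/- cells. The means of the distal nephron and proximal tubule genes were below 0 as well (-0.25 and -0.14), without a call that held across the alternatives. Of 15 urothelial and squamous genes 11 fell and 0 rose, and 12 fell adjusted over the list alone. The cornified envelope protein Ivl fell by 1.24 ± 0.09, the keratins Krt7 and Krt19 by 0.82 ± 0.07 and 0.77 ± 0.06, and Sfn by 0.75 ± 0.07. The list had a camera adjusted p of 2.08e-07, 0.278 with an estimated correlation, and 0.0150 against no change by fry. Of 21 genes of the loop of Henle, distal tubule and collecting duct 6 fell and 0 rose, and 6 fell and 1 rose adjusted over the list alone. The sodium channel subunit Scnn1a fell by 1.22 ± 0.08, Hsd11b2, which inactivates glucocorticoids in the collecting duct, by 1.10 ± 0.11, the transcription factor Gata3 by 0.78 ± 0.08, and Cldn19 was at least 1.44-fold lower. With normexp Ivl and Hsd11b2 fell by 0.79 and 0.66, and Cldn19 no longer passed (-0.19, adjusted p = 0.172). That list passed narrowly (camera adjusted p = 0.0471), with adjusted p = 0.525 with an estimated correlation, and its median of -0.10 became 0.03 with median scaling. It did not pass in 10 of 23 alternatives. Besides the estimated correlation these were quantile normalization (adjusted p = 0.400), scaling by detected probes (0.0696), dim probes kept (0.0746), only probes measured on all 4 arrays (0.0833), wild type replicate 2 left out (0.105), SerpinB2-/- replicate 1 left out (0.123), the region around Serpinb2 left out (0.0873), genes of more than 1 list left out (0.0504), and fry against no change (0.106). Of 32 proximal tubule genes 2 rose and 4 fell, and 2 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.0764). That list passed downward against no change by fry (adjusted p = 0.0150), and against other genes with the mean of a gene's probes (0.0412), with every probe by itself (0.00734) and with median scaling (0.0310), where its median of -0.11 became 0.01. Alpl and Hnf4a rose by 0.98 ± 0.11 and 0.57 ± 0.08, and Anpep and Slc16a9 fell by 0.60 ± 0.09 and 0.57 ± 0.08. With normexp Alpl was at 0.62 and Slc16a9 at -0.28.

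Markers of tubular injury went both ways, with 3 of 33 higher and 4 lower, and 5 higher and 6 lower adjusted over the list alone. Fgb rose and Lcn2 fell, as above, and Itgb6 and Il24 fell by 0.83 ± 0.07 and 0.50 ± 0.08. With normexp Il24 no longer passed (-0.25, adjusted p = 0.0632). Havcr1, the kidney injury molecule, differed by 0.12 ± 0.07 (adjusted p = 0.257). The list's median was 0.04, which became -0.01 with quantile normalization, its mean -0.02 and its camera test upward (adjusted p = 0.839).

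**Figure D2:**
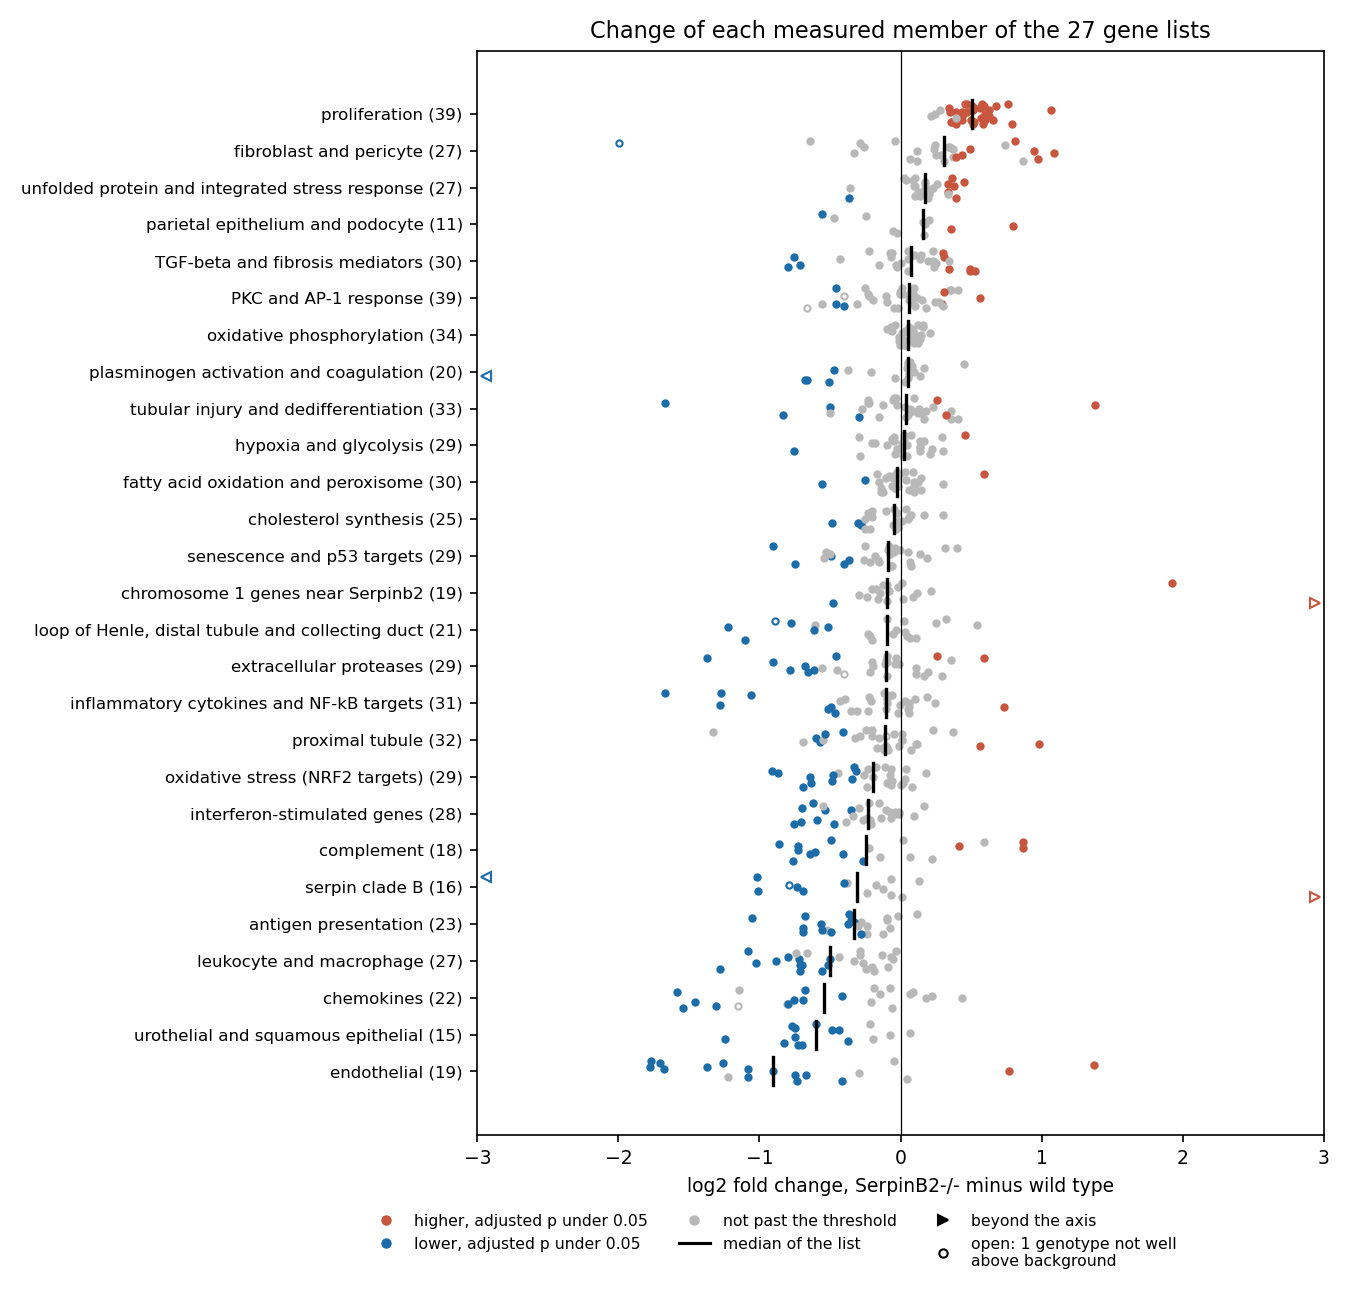
Log2 fold change, SerpinB2-/- minus wild type (horizontal axis), of every measured member of the 27 gene lists, with the number of measured members in brackets. Colour marks genes past the threshold, the black line the list's median, open symbols genes not well above background in 1 genotype, and triangles the fitted values of Serpinb2 and Serpinb10 beyond the axis. The medians ran from -0.91 for endothelial markers to 0.51 for proliferation genes.

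In the plasminogen system, the urokinase gene Plau fell by 0.68 ± 0.12 (adjusted p = 0.0275). Its receptor Plaur (0.08 ± 0.09) and the tissue activator Plat (-0.21 ± 0.08) did not pass the threshold. Of 20 genes of plasminogen activation and coagulation 5 fell and 0 rose, also adjusted over the list alone. They were Serpinb2, Plau, thrombomodulin Thbd (-0.66 ± 0.07), the protein C receptor Procr (-0.51 ± 0.06) and tissue factor F3 (-0.47). Endothelial markers were lower in the same samples, with a list median of -0.91. The list's median was 0.05, its mean -0.53 and its camera test downward (adjusted p = 0.339, and 0.0163 against no change by fry). The mean rested on the fitted value of Serpinb2, and was -0.09 without it. The fry test included this deleted gene and was not repeated without it. Of 16 clade B serpins 7 fell, the deleted Serpinb2 among them, and 1 rose, its neighbour Serpinb10. Adjusted over the list alone 10 fell and 1 rose. The list had a camera adjusted p of 0.00193, 0.476 with an estimated correlation, and 0.026 against no change by fry. The camera call at the preset correlation stayed without Serpinb2 and Serpinb10, and fry was not repeated without them. Serpinb9e and Serpinb9f fell by 1.01 ± 0.12 and 1.02 ± 0.13. With normexp these falls were 0.49 and 0.48. Among 29 extracellular proteases and their inhibitors 7 fell and 2 rose, also adjusted over the list alone. The membrane serine proteases Tmprss2, Prss8 and St14 fell by 1.37 ± 0.07, 0.90 ± 0.07 and 0.78 ± 0.06, and Mmp24, well above background on 1 of the 2 SerpinB2-/- arrays, by 0.68 ± 0.10. A further probe of Mmp24 gave -0.17, and with normexp the gene no longer passed (-0.20, adjusted p = 0.131). Against no change the protease list passed by fry (adjusted p = 0.0150). Camera gave an adjusted p of 0.0365, with adjusted p = 0.476 with an estimated correlation. That call ended without wild type replicate 1 (adjusted p = 0.0822), with scaling by detected probes (0.0653), with only probes measured on all 4 arrays (0.0590) and with the mean of a gene's probes (0.0870), and the list's median of -0.10 became 0.02 with median scaling.

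Stress responses moved in different directions, in samples that also had lower leukocyte and endothelial lists (medians -0.50 and -0.91) and a higher fibroblast list (0.31). Of 29 NRF2 targets 10 fell and 0 rose, and 13 fell adjusted over the list alone. Nqo1 fell by 0.91 ± 0.16, haem oxygenase Hmox1 by 0.64 ± 0.09 and the glutathione transferases Gsta3 and Gsta2 by 0.87 ± 0.07 and 0.69 ± 0.15. The list had a camera adjusted p of 9.35e-05, 0.278 with an estimated correlation, and 0.0152 against no change by fry. Of 27 genes of the unfolded protein and integrated stress response 6 rose and 1 fell, and 7 rose and 2 fell adjusted over the list alone. Psat1 rose by 0.45 ± 0.08 (0.23 at a further probe), Herpud1 by 0.40 ± 0.07, Mthfd2 by 0.38 ± 0.06 and Manf by 0.37 ± 0.06. The list had a camera adjusted p of 0.000223, 0.525 with an estimated correlation, and 0.123 against no change by fry.

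The other lists did not pass by camera, which tests for a shared direction, though some did under single alternatives. A form of fry that disregards direction passed all of the 27 lists but oxidative phosphorylation (adjusted p = 0.161). Of 18 complement genes 9 fell and 3 rose, and 10 fell and 4 rose adjusted over the list alone (camera adjusted p = 0.0681). The list passed downward with normexp (adjusted p = 0.0333), median scaling (0.00764) and dim probes kept (0.0225). C5ar1 and C1qa fell by 0.86 ± 0.08 and 0.76 ± 0.08, and Serping1 and C1s1 rose by 0.87 ± 0.11 and 0.87 ± 0.10. In the same samples the leukocyte and macrophage list was lower (median -0.50) and the fibroblast and pericyte list higher (median 0.31). Of 30 TGF-beta and fibrosis genes 6 rose and 3 fell, and 11 rose and 3 fell adjusted over the list alone (adjusted p = 0.120). The fibroblast markers above were higher in these samples. Among the 30, Tgfb3 rose by 0.53 ± 0.09, and E-cadherin Cdh1, Tgfbi and Bmp7 fell by 0.79 ± 0.06, 0.76 ± 0.06 and 0.71 ± 0.06. Of 39 genes of the protein kinase C and AP-1 response 3 rose and 3 fell, and 6 rose and 4 fell adjusted over the list alone (adjusted p = 0.615). Their median was 0.06, their mean -0.00447 and the camera test upward. Egr2 rose by 0.56 ± 0.07 and Junb fell by 0.40 ± 0.05. Of 11 podocyte and parietal genes 2 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.476), with Wt1 at 0.80 ± 0.14. The counts over all genes and over the list alone were 3 and 6 lower with 0 and 1 higher of 25 for cholesterol synthesis (adjusted p = 0.108), which passed downward with quantile normalization (0.0268), without wild type replicate 2 (0.00848) and without SerpinB2-/- replicate 2 (0.0305). For hypoxia and glycolysis they were 1 and 1 higher with 1 and 1 lower of 29 (0.481), and for fatty acid oxidation 1 and 1 higher with 2 and 0 lower of 30 (0.861). Of 34 oxidative phosphorylation genes 0 passed (adjusted p = 0.0712, over the list alone 0), the smallest p values being those of Ndufa5 (0.21 ± 0.08) and Cox5b (0.15 ± 0.05), both at an unadjusted p under 0.05. That list passed upward with median scaling (adjusted p = 0.0224), with every probe by itself (0.0203) and without wild type replicate 1 (0.0117).

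Around Serpinb2 on chromosome 1, further genes changed strongly. Of 19 measured genes of the list fixed for this region 2 rose (Serpinb10 and Inhbb) and 1 fell (Bcl2, -0.48 ± 0.06), also adjusted over the list alone. The list's median was -0.09, which became 0.03 with median scaling, its mean 0.44 and its camera test downward (adjusted p = 0.839). The mean rested on the fitted value of Serpinb10, and was 0.02 without it. By the probe positions of the files, 11 of 132 tested genes within 20 Mb of Serpinb2 passed the threshold with a fitted change of at least 2-fold (8.33%), against 241 of 18071 genes elsewhere (1.33%, two-sided Fisher's exact p = 2.28e-06). Such genes numbered 1 of 21 within 5 Mb, 3 of 28 within 10 Mb and 12 of 380 within 40 Mb, so that most of the 11 lay 10 to 20 Mb away. Cntnap5a lay at 118477133, Inhbb at 121312160, Stk25 at 95518612, Pam at 99718052 and St8sia4 at 97484331. Of the 11, Serpinb10, Mlph, Agxt, St8sia4 and Cntnap5a were not well above background in 1 genotype. The share was not recounted under the alternatives. With normexp St8sia4 was at -0.63, short of 2-fold, while Cntnap5a at -1.05 and Serpinb10 at 4.72 were not. Fisher's test treats genes as independent, also where they lie side by side.

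**Figure D3:**
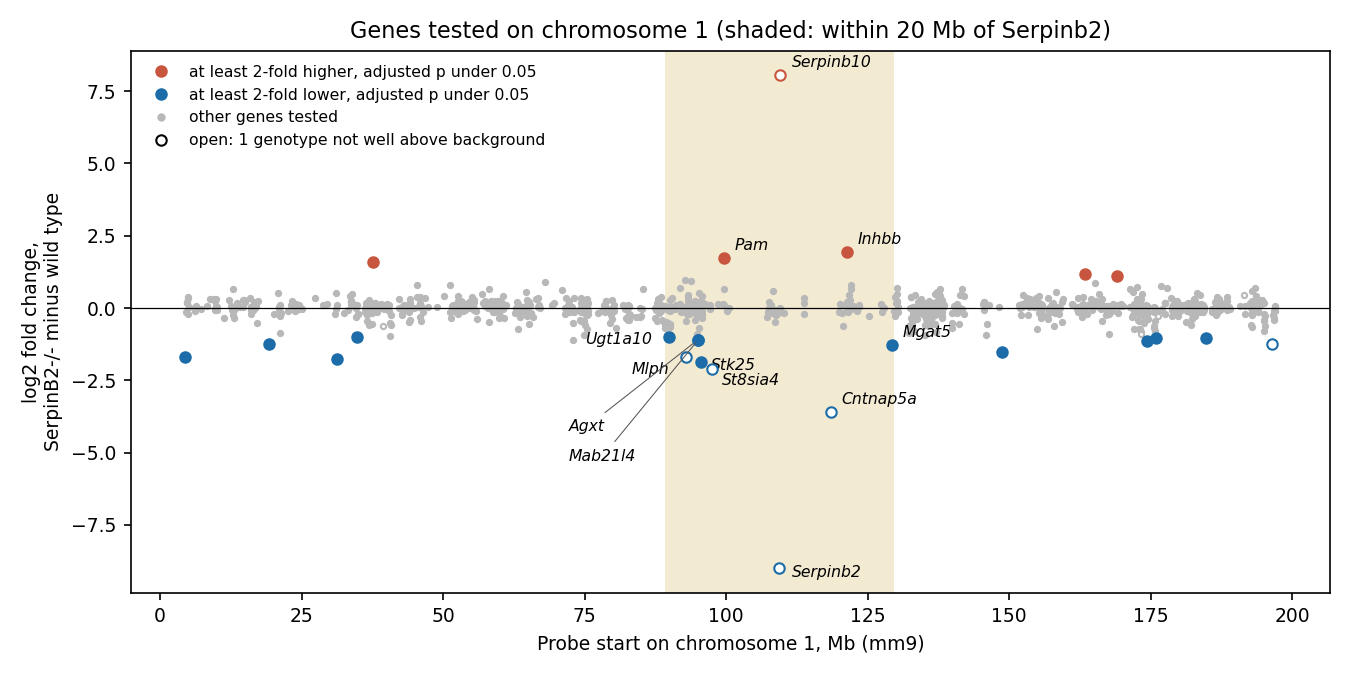
Log2 fold change, SerpinB2-/- minus wild type (vertical axis), of the genes tested on chromosome 1 against the start of their probe in Mb on mm9 (horizontal axis), each point a gene. The shaded band spans 20 Mb to each side of Serpinb2, coloured points passed the threshold with a fitted change of at least 2-fold, and open symbols mark genes not well above background in 1 genotype. In the band 11 of 132 genes besides Serpinb2 are coloured, against 12 of 890 on the rest of the chromosome.

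The labels give all 4 samples as male with a B6.J background. Xist, the X-linked transcript of the inactive X chromosome, was well above background on 4 of 4 arrays at both of its probes, with signals of 613 to 897 units at the brighter one. The 5 probes of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were not well above background on any array. Another 7 transcripts whose probes the files place on chromosome Y, named only by clone, probe or prediction, were well above background on all 4 arrays. The brightest probe of Nnt, a gene partly deleted in C57BL/6J mice, gave a log2 signal of 1.67 and 1.64 in wild type and 1.67 and 1.77 in SerpinB2-/- cells. Another probe was at background on all arrays and a dim one was well above it in wild type only. The files do not show whether any of these probes lies in the deleted part, so their signals do not tell the substrain.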

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

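The unplanned alternatives were spots marked as outliers kept, the chromosome 1 window left out, and the lists without Serpinb2 and Serpinb10. Serpinb2 was lower in all 17 alternatives that gave it a value (log2 -9.21 to -5.69, largest adjusted p 0.0176). Of 2333 values of named genes under the alternatives, 1969 stayed on their side of the threshold, 360 lost the call, 4 gained it and 0 called values changed sign. Of 620 list values 565 stayed, 40 lost and 14 gained the call. The list of chromosome 1 genes turned from down to up by fry (mean 0.44, adjusted p = 0.0439), a mean that was 0.02 without Serpinb10. Of the 15 lists past the threshold 0 remained by camera with an estimated correlation (lowest adjusted p 0.278). That form of camera had few residual degrees of freedom. By fry, which tests against no change, 8 of the 15 lost the call. Fry for a shared direction passed 10 lists in all, among them the proximal tubule, plasminogen and chromosome 1 lists, which were not among the 15. The plasminogen list held the deleted Serpinb2 and the chromosome 1 list held Serpinb10, and fry was not repeated without these genes. The clade B serpin list held both genes. With all 4 arrays the other alternatives passed 13 to 18 lists in all. Genes past the threshold numbered 4 to 1779 with an array left out (1 to 575 higher, 3 to 1204 lower), the lone array being assumed to vary like the others. They numbered 3 with dim probes kept (1 higher, 2 lower) and 4773 with median scaling (3532 higher). A trended fit gave 1738 higher, an adjusted p under 0.1 gave 4853 (2106 higher, 2747 lower), at least 2-fold gave 255 (31 higher, 224 lower), and an unmoderated test gave 0 (0 higher, 0 lower). For all of these differences the cause was not tested. The labels give the samples a number and do not say what it marks: same-numbered samples deviated with r = 0.262 across genes, and with the replicate block 2070 genes passed, 658 of them higher. The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The split by genotype gave 2877 genes by limma and was the 1 split of 3 with as many, and the highest other count was 0 (106 and 302 genes at an unadjusted p under 0.05).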

Other observations

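The test on the share of tubular cells, that on bright endothelial markers, those on the sex of the cells and the list of early embryo genes were chosen after the values were seen. A set of genes was higher on the replicate 2 array of both genotypes than on the replicate 1 array, a difference that crosses the comparison of genotypes. At least 4-fold higher in both were 30 of 18392 genes, and 0 were lower by as much. Among them were Zscan4a and Zscan4c, which are transcribed in 2-cell embryos and in a small share of embryonic stem cells, the deubiquitinases Usp17la and Usp17lc, and Pramel31, Pramel39, Gm2022 and Gm4340. The log2 signal of Gm4340 was -5.05 and -1.37 in wild type replicates 1 and 2, and -3.51 and -0.91 in SerpinB2-/- replicates 1 and 2. For Usp17lc it was -5.99 and -2.80, and -4.80 and -2.53. For Zscan4c it was -7.15, not well above background, and -2.69 in wild type, and -5.45 and -3.29 in SerpinB2-/- cells. Of 27 genes of early embryos and embryonic stem cells, 24 were on the array, 16 were well above background on at least 1 array, and 10 were at least 2-fold higher on both replicate 2 arrays. The list was written after the replicate values were seen and holds 6 genes that had already stood out, so its count is no independent evidence. Tcstv1 and Tcstv3 were among the 10, and Nanog (-3.60, -3.73, -3.83 and -3.81) and Zfp352 (0.15, 0.07, 0.10 and 0.46) were not. Several of these genes belong to families of near-identical copies, which a probe may not tell apart, and between genotypes Zscan4f differed by 0.65 ± 1.53 (adjusted p = 0.794).

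Genes changed at least 2-fold around Serpinb2 were more frequent than independent placement by chance gives, which was not recounted under the alternatives. The two-sided Fisher's exact p was 2.28e-06 against all other genes. Within chromosome 1 the share was also higher near Serpinb2 than on the rest (11 of 132 against 12 of 890, two-sided Fisher's exact p = 3.85e-05). A segment of chromosome from another strain, carried along with the deleted gene, may give such a cluster, and so may an effect of the deletion on its neighbours, which was not tested. A sequence variant under single probes cannot be told apart from a change in transcript: only 2 of the genes had a further probe, with a median ratio of 0.43 between the further and the brightest probe (1.02 for Ugt1a10, -0.16 for Pam).

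The endothelial and leukocyte markers were lower in SerpinB2-/- cultures under every scaling run, the highest endothelial median being -0.64, which argues against scaling as the cause. A lower share of tubular cells in wild type, if it raised all other cell types alike, would move their lists in 1 direction. Instead the fibroblast median exceeded the endothelial one by 1.21, with 7 fibroblast genes higher and 13 endothelial genes lower. The fibroblast list did not pass by fry (adjusted p = 0.281). This test cannot exclude a lower tubular share made up by only some of the other cell types. Of 5 bright endothelial markers 4 rose or had a 95% interval above the list's median, such as Kdr (0.05 ± 0.11) and Flt1, and so did 3 of 14 dimmer ones, and by the prediction as written this spoke against fewer endothelial cells in the SerpinB2-/- cultures. The explanation was first judged excluded and was put back to undecided after these values were seen, because bright markers may also be transcribed by other cells in the culture, so that the composition of the cultures and regulation by genotype cannot be told apart.

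The label male was at odds with part of the signals. Of the 5 probes of Ddx3y, Eif2s3y, Kdm5d and Uty, 0 were well above background on any array, while Xist was on 4 of 4. Y-linked probes that do not report would leave the Xist signal on 4 of 4 arrays unaccounted for. A sex of the cells other than labelled could not be settled, because 7 other transcripts placed on chromosome Y were well above background on all arrays, and without a genome it could not be checked whether their probes also match other chromosomes. For the sex label no further explanation was tested.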
